A study of Mus musculus with 40 samples.

How the data were processed

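Poly(A)-selected RNA of 20 immortalised brown preadipocyte lines, undifferentiated and after 8 days of differentiation, was sequenced as 100 bp read pairs from a strand-marking library kit, per the labels' protocols. Differentiation was induced with IBMX, dexamethasone, indomethacin, T3 and insulin, and T3 and insulin were kept in the medium afterwards, per the labels' protocols. Reads were aligned with STAR to mouse build mm9 and counted per gene with HTSeq, per the submitters' processing notes. The versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of an overlapping antisense gene may therefore not be separated in every case. The deposited files hold whole-number counts per gene symbol, not normalised, for 1 library each, and they give no gene coordinates, so no positions are stated.

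The files of the 2 stages differ in how they were made. Undifferentiated files list 29955 symbols and differentiated files 29915, with 43 and 3 symbols found in 1 stage only. The tallies that the authors' counting adds to each file were left out of library sizes and tests. Reads without a gene made up 7.17% ± 0.356 (SD, n = 20) of all tallied reads in undifferentiated and 4.77% ± 0.267 in differentiated libraries, ambiguous reads 3.27% ± 0.0537 and 3.69% ± 0.0668, and reads aligned to several places 16.8% ± 0.456 and 12.8% ± 1.02. Reads of low quality and unaligned reads averaged 735418 and 243009 per undifferentiated library, whereas both tallies were 0 in all 20 differentiated libraries. No library of one stage was counted like the other, so the stage and the counting cannot be told apart. Of the 29912 shared symbols, 125 that differ from another symbol only in letter case were left out, since the files may treat them differently, and 29787 were kept, of which 6941 were at 0 in all 40 libraries.

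The 50 most abundant genes took 8.50% ± 0.647 of the counts in undifferentiated and 8.85% ± 0.530 in differentiated libraries. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by stage (minimum count 10), libraries were scaled with TMM, and log2 CPM used a prior count of 2. Tests used edgeR's quasi-likelihood F-test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Limits for 0 counts use 3 counts, and intervals for single libraries and for ratios with 1 to 3 counts are exact binomial intervals at 95%.

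The stage difference was fitted over all 40 libraries without a block. The cell line, which the labels give for every library, pairs the libraries of the 2 stages: the same line was grown in both. Stage-centred profiles of the 2 libraries of a line correlated at 0.336 to 0.645 in all 20 lines. The fit with the line as a replicate block called 12056 genes, against 11562 without it. The line difference was tested through all line coefficients next to the stage. Expression of the 20 undifferentiated libraries was tested against the later adipocyte score and the later Ucp1 of the line as continuous covariates, and that of the 20 differentiated libraries against Ucp1 with the adipocyte score as a second covariate, so that no line was put into a group by its outcome. Relations between measures across lines, the similarity of the libraries of a line and the spread between lines were tested by permutation of lines, or of the stages within lines. One more planned relation, with Ppargc1a, was not computed because that gene was listed at 0 in all libraries.

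Gene lists were fixed before the data were examined. They cover adipocyte differentiation, thermogenic, white and beige adipocyte, lipogenesis, fatty acid oxidation, tricarboxylic acid cycle, nuclear-encoded respiratory chain, mitochondrially encoded, cell cycle, extracellular matrix and cytoskeleton, preadipocyte, skeletal muscle, pericyte and smooth muscle, endothelial, immune, Schwann and neural, glucocorticoid, interferon, integrated stress response, glycolysis, Hox, sex-linked and study subtype genes. Lists were set against all other genes with camera (preset correlation 0.01, then an estimated one). Beside it fry was run, which tests a list without setting it against other genes. Both were adjusted over the 22 lists with at least 3 tested genes. Between lines, the share of called members was set against 10000 random lists matched on mean expression.

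Genes named in the text follow a rule fixed before the data were examined. For the stage they are the 10 steepest rises and the 10 steepest falls among called genes with a mean of at least 10 CPM in the higher stage and a shared direction in 20 of 20 lines, plus a fixed set of markers. For the lines they are the 15 called genes with a mean of at least 10 CPM and the largest SD between lines. For each covariate they are the 5 positive and 5 negative called genes with the smallest p and a mean of at least 5 CPM. For each list they are up to 4 called members with the largest change and at least 5 CPM in the higher stage, and up to 2 that went against the majority. Gapdh, Ppia, Rpl19, Ptprc, Pecam1 and Hox genes singled out between lines were in part chosen after their values were seen.

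Sequence shared with processed pseudogenes was measured as the percent of the 31-mers of a gene's annotated protein-coding transcripts that occur in transcripts annotated as processed pseudogenes, in a GENCODE annotation of build GRCm38. That build is later than the one the authors used, and it served only for sequence and for the chromosome of a symbol. Of the 14081 tested genes, 80.8% had a value. Pseudogene copies that the annotation does not list were not searched. This check was added after the data were examined.

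The edgeR tests of stage, line, covariates and letter were tested on simulated data drawn from the means and library sizes of the real libraries, with 200 changed genes, 50 of each size. For the stage difference over 14081 simulated genes, 10% of changes of 1.2-fold, 74% of 1.5-fold, 78% of 2-fold and 96% of 4-fold were recovered, with 4 false calls among 133. For the line difference, 24% of genes with an added SD between lines of 0.25 (log2), 68% at 0.5, 74% at 1 and 100% at 2 were recovered, with 6 false calls among 139. Simulated genes were drawn independently of each other and few were changed. The simulation therefore does not cover correlated genes or a difference as broad as the 11562 genes called for the stage. The list tests, relations, own-line similarity and spread test were not simulated. Alternatives were other scaling, count filters, DESeq2, limma-voom, the replicate block, leaving out lines, ranks in place of covariates, and other gene numbers and prior counts.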

Results

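Gene-level read counts were analysed for 20 immortalised cell lines derived from the brown fat of C57BL/6 mice, the tissue that burns lipid to produce heat. Each line gave 1 library of undifferentiated preadipocytes and 1 library of cells taken 8 days after induction of adipocyte differentiation, so that 40 libraries fell into 2 groups of 20. The lines carry a letter from A to D and a number, and the labels do not say what the letter stands for. Total counts on genes ranged from 19535806 (line A5) to 28074918 (B4) in undifferentiated libraries and from 27181830 (B3) to 43113838 (B6) in differentiated libraries. The upper limit that 0 counts allows, 3 counts, was 0.107 to 0.154 CPM (the usual unit of counts scaled to library size) in undifferentiated libraries and 0.0696 to 0.110 CPM in differentiated ones. Such limits, and the intervals given for single libraries, cover counting error only. Levels are given as normalised CPM, mean ± SD over the 20 lines of a stage. Each line was cultured once per stage in these data, so the spread between lines includes the noise of culture and library preparation.

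The first comparison asked which genes changed when the preadipocytes were differentiated for 8 days. Several genes of fat storage and fat-cell hormones, close to or below detection before induction, were abundant afterwards, while others such as Lpl, the lipoprotein lipase, and Acsl1 started at 56.0 and 56.7 CPM. Adipoq, which encodes the hormone adiponectin, rose from 0.0164 ± 0.0207 CPM to 803 ± 311 CPM (SD, n = 20 per stage). Plin1, a lipid droplet coat protein, rose from 0.0133 ± 0.0259 to 411 ± 173 CPM, and the fatty acid transporter gene Cd36 rose from 0.00854 ± 0.0225 to 936 ± 408 CPM. Cfd, which encodes adipsin, had 0 counts in all 20 undifferentiated libraries and 673 ± 404 CPM after differentiation, which was at least 106947-fold higher against a limit of 3 counts over the group. The 2 central transcription factors of fat-cell formation rose from a higher starting level, Pparg from 47.2 ± 36.9 to 426 ± 177 CPM and Cebpa from 40.3 ± 35.1 to 468 ± 195 CPM. Fabp4, a fatty acid binding protein, rose from 8.64 ± 14.0 to 1140 ± 403 CPM. All 24 genes of the adipocyte differentiation list rose, with a median log2 fold change of 8.20, which was also the median with Cfd at its bound.

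The lines did not take part equally. Averaged over the adipocyte list, the rise on the log2 scale was 3.43 in line C6 and 6.16 in line D5, against 7.44 to 8.99 in the other lines. After differentiation Adipoq reached 15.3 CPM in C6 and 219 CPM in D5, and Pparg stood at 20.7 CPM in C6 against 28.2 CPM in the undifferentiated library of that line. Pparg was higher after differentiation in 19 of the 20 lines (log2 fold change 3.17, SE 0.32, adjusted p = 8.78e-12 in edgeR's quasi-likelihood test). Adipoq was higher in 20 of 20 lines (log2 fold change 15.23, SE 0.45, adjusted p = 2.15e-29 in the same test). Set against all other genes, the adipocyte list moved up with an adjusted p of 2.89e-11 in camera with its preset correlation between genes. That p was 0.460 with an estimated correlation.

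**Figure D1:**
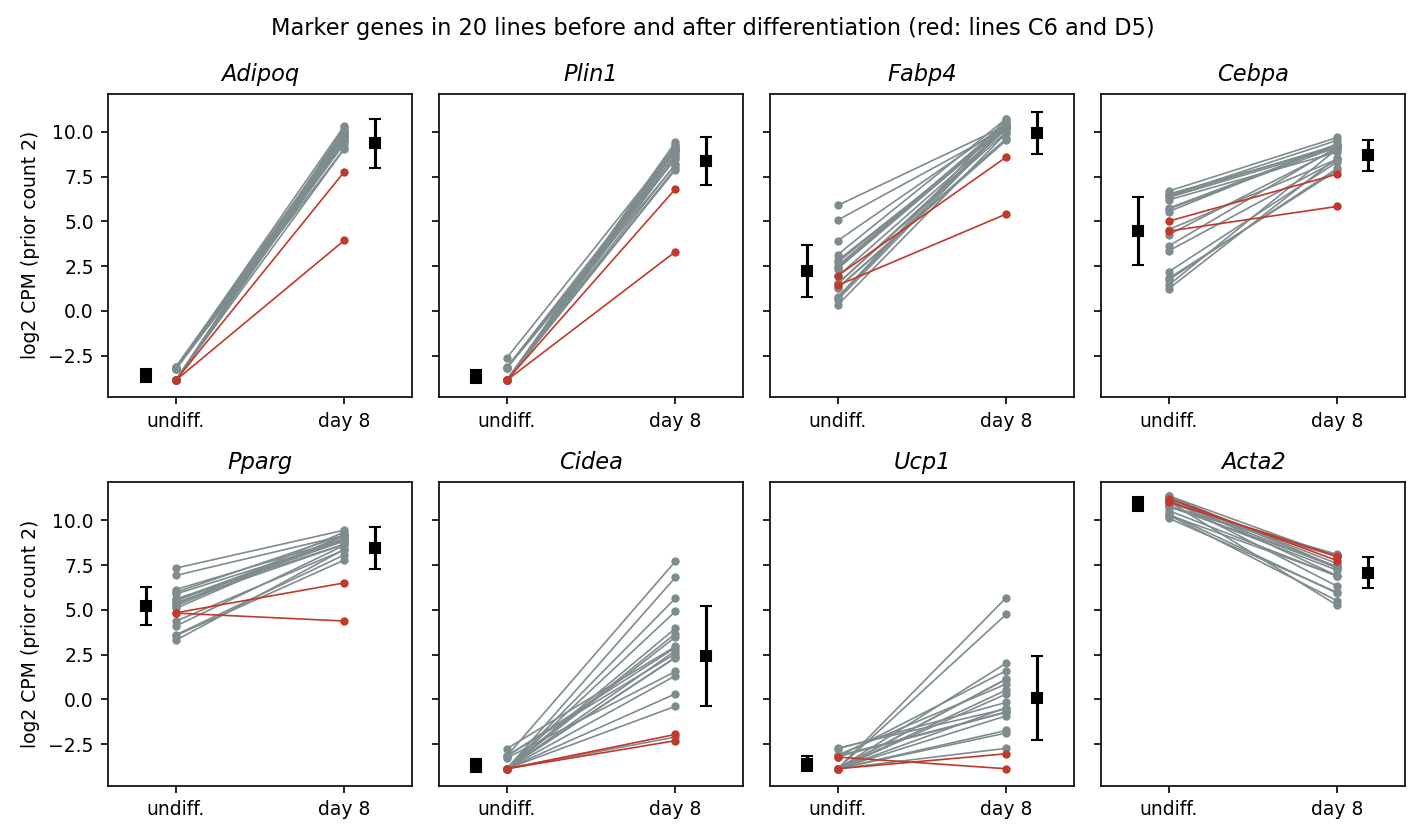
Levels of 8 marker genes (vertical axis, log2 CPM with a prior count of 2) in undifferentiated cells and at day 8. Each line joins the 2 libraries of 1 cell line, lines C6 and D5 are in red, and squares with bars give the mean and SD over 20 lines. Adipoq rose in all 20 lines and least in C6, while Ucp1 at day 8 was highest in B6 and B3.

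Genes of the thermogenic brown adipocyte rose together but unevenly between lines. Of the 17 tested members of that list, 15 rose and 2 were not called, with a median log2 fold change of 4.27 (camera adjusted p = 0.00182, and adjusted p = 0.460 with an estimated correlation). Adrb3, the beta-adrenergic receptor of fat cells, rose from 0.461 ± 0.349 to 155 ± 94.0 CPM. The potassium channel gene Kcnk3 rose from 0.470 ± 0.692 to 134 ± 103 CPM, and Cox7a1, a respiratory complex subunit, rose to 50.6 ± 33.4 CPM with a log2 fold change of 7.62. Cidea, a lipid droplet protein enriched in brown fat, rose from 0.0123 ± 0.0233 to 24.3 ± 50.6 CPM, with 209 CPM in line B6 and 0.135 CPM in line D5. Prdm16, a regulator of brown fat identity, rose from 1.61 ± 1.88 to 6.24 ± 4.75 CPM. Dio2, the thyroid hormone deiodinase, stood at 0.0685 ± 0.218 and 0.145 ± 0.285 CPM and was not called by edgeR without a count filter and without the line as a block (adjusted p = 0.198). It was called with the replicate block (0.0178) and by DESeq2 (0.000439), and not by limma-voom (0.0529). Ppargc1a was listed at 0 in all 40 libraries, which does not tell absent expression from a symbol that the counting did not cover. The white and beige adipocyte list had 11 genes that rose, 1 that fell and 4 not called (camera adjusted p = 0.0181, and adjusted p = 0.417 with an estimated correlation). In that list Agt, angiotensinogen, rose from 0.323 ± 0.392 to 244 ± 206 CPM and Sncg from 1.29 ± 3.06 to 147 ± 105 CPM. Lep, leptin, had 0 counts before and 15.6 ± 20.1 CPM after differentiation, at least 2479.7-fold higher against 3 counts over the group, and the transcription factor gene Tbx15 fell from 155 ± 88.5 to 89.3 ± 68.1 CPM.

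Ucp1, the uncoupling protein through which brown fat makes heat, stayed low in most lines and did not pass the count filter. The 20 undifferentiated libraries held 9 Ucp1 counts in all and the 20 differentiated libraries 3525, of which 2191 came from line B6 alone. Scaled by the plain library total, the differentiated library of B6 held 51.1 CPM (95% exact binomial interval 48.9 to 53.2), that of B3 25.3 (23.4 to 27.2) and that of D6 3.96 (3.34 to 4.66). Every other line was at or below 2.76 CPM. Line C6 had 0 counts. In edgeR without a count filter, Ucp1 rose with a log2 fold change of 7.74 (SE 0.95, adjusted p = 1.42e-09) and was higher in 19 of 20 lines.

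Lipid metabolism and nuclear-encoded genes of mitochondrial metabolism moved up with differentiation. Of 16 lipogenesis genes, 15 rose and 1 fell (camera adjusted p = 1.45e-05, and adjusted p = 0.460 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, rose from 231 ± 53.9 to 7435 ± 2858 CPM, Thrsp from 0.0215 ± 0.0290 to 317 ± 120 CPM and Acacb from 2.62 ± 0.794 to 217 ± 212 CPM, whereas the elongase gene Elovl6 fell from 7.55 ± 1.83 to 5.38 ± 1.81 CPM. In fatty acid oxidation 19 of 20 genes rose, including Ehhadh, from 1.01 ± 0.992 to 22.3 ± 12.9 CPM, and Ech1, from 36.1 ± 6.48 to 235 ± 88.6 CPM (camera adjusted p = 3.06e-06, and adjusted p = 0.460 with an estimated correlation). All 22 genes of the tricarboxylic acid cycle list rose, led by Pcx, the pyruvate carboxylase, from 36.0 ± 5.54 to 1349 ± 464 CPM (camera adjusted p = 6.66e-05, and adjusted p = 0.463 with an estimated correlation). All 43 nuclear-encoded respiratory chain genes rose, with a median log2 fold change of 1.12 (camera adjusted p = 1.47e-08, and adjusted p = 0.460 with an estimated correlation). Of the mitochondrially encoded list only mt-Nd4 matched a symbol in the files, and it rose from 305 ± 33.1 to 421 ± 195 CPM, with higher values in 11 of 20 lines. Symbols outside the list that read as mitochondrially encoded genes did not rise. Cytb stood at 880 ± 76.2 and 819 ± 337 CPM and was not called. Cox2 and Atpase6 fell, to 0.461 ± 0.256 and 1.08 ± 0.570 CPM, with log2 fold changes of -3.66 and -4.84. Scaled by the plain library total, Cox2 and Atpase6 started at only 5.94 ± 0.849 and 31.4 ± 4.86 CPM, far below Cytb. Whether these 2 symbols hold the reads of the mitochondrial genes was not tested. Their fall cannot be told apart from the different counting of the 2 stages.

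Part of these changes lay in genes whose sequence is shared with processed pseudogenes, the intron-less copies of mRNAs scattered over the genome. The files of the 2 stages were counted under different settings, as their tallies of discarded reads showed, and stage and counting cannot be told apart in this design. Among 11379 tested genes with a protein-coding transcript in the annotation used, 694 had at least 10% of their 31-mers in annotated processed pseudogenes. Of these, 462 rose, 161 fell and 71 were not called. Their median log2 change was 0.69, above each of 10000 random lists matched on expression, whose highest median was 0.0832. Gapdh, a glycolysis enzyme with 61.4% of its 31-mers shared, went from 28.0 ± 4.30 to 1417 ± 466 CPM. Ppia, a prolyl isomerase with 25.4% shared, went from 11.4 ± 1.26 to 521 ± 43.7 CPM, and the ribosomal protein gene Rpl19, with 74.5% shared, from 13.4 ± 2.43 to 550 ± 59.3 CPM. The same caution applies to Hadhb (62.1% shared, 10.1 ± 1.21 to 309 ± 157 CPM), Pdhb (41.9%, 71.5 ± 17.9 to 551 ± 295 CPM), Atp5h (46.0%, 19.8 ± 3.66 to 269 ± 74.6 CPM), and Cycs (10.1%, log2 fold change 5.15). Without the genes at or above 10%, all 32 remaining respiratory chain genes and all 19 remaining tricarboxylic acid cycle genes still rose, and the adipocyte and thermogenic lists held no such gene, nor did the extracellular matrix list among its measured members (Ctgf and Cyr61 had no value). Sequence shared with annotated processed pseudogenes did not cover every steep rise, since Cox5b, with 0% shared, went from 8.05 ± 1.17 to 165 ± 60.9 CPM.

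**Figure D2:**
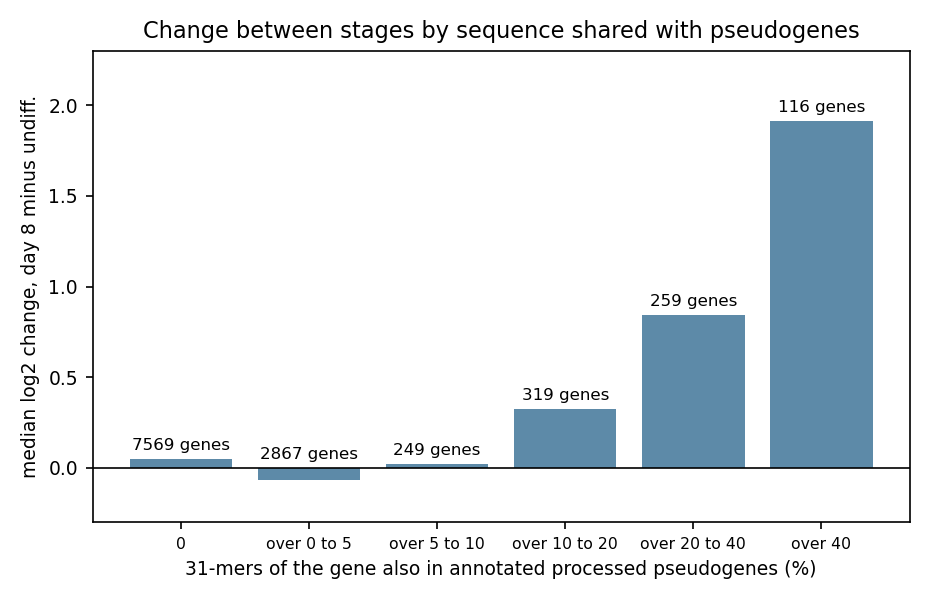
Median log2 change between stages (vertical axis, day 8 minus undifferentiated) of tested genes grouped by the percent of their 31-mers also found in annotated processed pseudogenes (horizontal axis). The number of genes stands at each bar. The median was 0.05 for the 7569 genes with 0% shared and 1.91 for the 116 genes with over 40% shared.

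The glycolysis list shows the weight of this caution. Of its 18 genes 13 rose and 1 fell (camera adjusted p = 0.00295, and adjusted p = 0.460 with an estimated correlation), but 9 members carried at least 10% of shared sequence. Among them, Pgk1 went from 35.5 ± 6.10 to 756 ± 278 CPM with 68.3% shared and Pgam1 from 20.0 ± 3.09 to 287 ± 85.6 CPM with 42.1% shared. Without those 9, 5 genes rose, 1 fell and 3 were not called, and the camera adjusted p was 0.269. Hk1, a hexokinase with 0% shared, fell from 150 ± 22.2 to 112 ± 36.3 CPM.

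Cell cycle genes and genes of the extracellular matrix and cytoskeleton mostly moved down. Of 29 cell cycle genes, 21 fell and 4 rose (camera adjusted p = 0.000302, and adjusted p = 0.460 with an estimated correlation). Mki67, a proliferation marker, fell from 479 ± 73.7 to 251 ± 76.9 CPM in 20 of 20 lines. The mitotic kinase gene Bub1 fell from 142 ± 18.4 to 47.1 ± 11.9 CPM and Rrm2, which supplies deoxynucleotides, from 326 ± 96.7 to 90.3 ± 27.2 CPM. Pcna, the replication clamp, rose from 110 ± 12.2 to 325 ± 35.7 CPM with 38.0% of its 31-mers shared with pseudogenes, and without the genes with copies 17 members fell and 1 rose. Of 24 extracellular matrix and cytoskeleton genes, 16 fell and 4 rose (camera adjusted p = 0.00469, and adjusted p = 0.507 with an estimated correlation). The smooth muscle actin gene Acta2 fell from 1957 ± 496 to 157 ± 76.5 CPM and Cnn1, calponin, from 199 ± 127 to 4.76 ± 3.68 CPM. Against that direction, the proteoglycan gene Dcn rose from 0.328 ± 0.388 to 136 ± 164 CPM and the collagen gene Col3a1 from 394 ± 330 to 2135 ± 2085 CPM, while Col1a1, at 2073 ± 1084 and 1808 ± 1639 CPM, was not called.

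Markers of preadipocytes and mesenchymal progenitors went both ways, with 7 that rose, 9 that fell and 5 not called (camera adjusted p = 0.439). The transcription factor genes Foxc2 and Gata2 fell, from 47.3 ± 13.7 CPM with a log2 fold change of -3.83 and from 94.9 ± 53.7 to 11.2 ± 8.43 CPM. The surface markers Pdgfra and Ly6a rose, from 76.7 ± 72.8 to 241 ± 206 CPM and, with a log2 fold change of 2.87, to 291 ± 241 CPM, as did the preadipocyte regulator Zfp423, from 3.17 ± 3.11 to 28.2 ± 11.7 CPM. Dlk1, an inhibitor of fat-cell formation, stood at 77.9 ± 83.4 and 204 ± 251 CPM and was higher in 15 of 20 lines. It was called by edgeR (adjusted p = 0.0281) and not by limma-voom (adjusted p = 0.187), with 0.00678 to 0.187 over the alternatives.

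Interferon-stimulated genes rose as a group. All 18 genes of the list rose, with a median log2 fold change of 4.95 (camera adjusted p = 1.32e-05, and adjusted p = 0.460 with an estimated correlation). The antiviral genes Mx1 and Ifit3 rose from 0.0745 ± 0.124 to 41.9 ± 47.3 CPM and from 1.55 ± 1.99 to 327 ± 243 CPM, and Ifi44 rose from 0.966 ± 2.33 to 184 ± 134 CPM, each in 20 of 20 lines. Of 12 glucocorticoid response genes, 10 rose and 2 fell (camera adjusted p = 0.00212, and adjusted p = 0.417 with an estimated correlation); the induction medium contained the glucocorticoid dexamethasone, per the labels' protocols. Fkbp5 rose from 106 ± 11.4 to 272 ± 102 CPM, Zbtb16 from 0.0260 ± 0.0358 to 73.2 ± 34.2 CPM and Tsc22d3 from 0.698 ± 0.293 to 8.87 ± 2.56 CPM, whereas the kinase gene Sgk1 fell from 231 ± 75.7 to 51.1 ± 48.6 CPM. Of 16 genes of the integrated stress response 10 rose and 2 fell, without a call for the list (camera adjusted p = 0.134). Trib3, a pseudokinase, rose from 8.73 ± 4.23 to 200 ± 132 CPM and Ddit3, a stress-induced transcription factor, from 30.9 ± 7.14 to 161 ± 110 CPM.

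Markers of other cell types were few among the tested genes. Of 4 tested skeletal muscle genes 1 rose and 2 fell (camera adjusted p = 0.868), of 7 pericyte and smooth muscle genes 4 rose and 3 fell (0.288), of 4 endothelial genes 2 rose (0.868), of 3 immune genes 2 fell (0.288) and of 5 Schwann and neural genes 4 rose and 1 fell (0.281). The intermediate filament gene Des, on both the skeletal and the smooth muscle list, rose from 0.557 ± 0.489 to 28.9 ± 21.6 CPM, and the nerve growth factor receptor gene Ngfr from 0.0839 ± 0.0966 to 36.5 ± 59.8 CPM. The pan-leukocyte gene Ptprc stood at 0.0248 and 0.0106 CPM and the endothelial gene Pecam1 at 0.133 and 0.644 CPM, neither past the count filter. Of 29 tested Hox genes, which mark position along the body axis, 3 rose, 11 fell and 15 were not called (camera adjusted p = 0.254). With the cell line as a replicate block, 8 rose and 14 fell. Adjusted over the list alone, 2 rose and 11 fell, and in every other list the counts adjusted over the list alone equalled those over all genes. Of 3 tested sex-linked genes, Eif2s3y rose from 43.3 ± 10.5 to 63.7 ± 34.8 CPM and the others were not called (camera adjusted p = 0.877). The 3 genes known as markers of brown adipocyte subtypes in this study were chosen on these lines and give no independent evidence. All 3 fell, Bin1 from 156 ± 26.2 to 59.0 ± 22.3 CPM, Eif5 from 416 ± 72.8 to 325 ± 79.1 CPM and Tcf25 from 387 ± 64.8 to 341 ± 61.4 CPM (camera adjusted p = 0.254 for the list).

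Over all genes, 6069 of 14081 rose and 5493 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Of these, 3468 rose and 3080 fell in all 20 lines, and 3330 rose and 2003 fell with a log2 change of at least 1. Among the 10 steepest rises with a shared direction in every line, Retn, resistin, went from 0.0190 ± 0.0348 to 372 ± 177 CPM. Car3, a carbonic anhydrase at 1144 ± 742 CPM after differentiation, had 3 counts before, a ratio of 174062 with a 95% exact counting interval of 59560.6 to 844045. Slc36a2, an amino acid transporter at 169 ± 84.2 CPM, had 2 counts before (ratio 39650.4, 10976 to 327410), and the apolipoprotein gene Apoc1 at 114 ± 52.1 CPM had 1 count (ratio 52560.3, 9433 to 2076050). BC034902 had 0 counts before and 78.1 ± 38.5 CPM after, at least 12405-fold higher against 3 counts over the group. Among the 10 steepest falls were the cartilage collagen gene Col2a1, from 130 ± 165 to 1.35 ± 0.697 CPM, the protease inhibitor gene Serpinb2, from 18.1 ± 10.4 to 0.182 ± 0.229 CPM, the protease gene Tll1, from 81.2 ± 48.6 to 0.979 ± 0.548 CPM, Shank2, from 15.8 ± 6.95 to 0.217 ± 0.203 CPM, and the troponin gene Tnnt2, from 10.2 ± 10.5 to 0.172 ± 0.161 CPM. Lce1g fell to 0.177 ± 0.244 CPM with a log2 fold change of -5.95, and Tmem171 from 46.7 ± 37.7 to 0.854 ± 1.23 CPM. The other 3 steepest falls carried clone or predicted-gene symbols, Gm5088 (90.1 ± 14.2 to 1.26 ± 0.531 CPM), AK199756 (65.8 ± 14.2 to 0.695 ± 0.427 CPM) and AK185530 (36.2 ± 4.12 to 0.615 ± 0.206 CPM).

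The second comparison asked whether the 20 lines differed from one another beyond the stage. Single genes separated the lines in both stages. Zic1, a transcription factor of brown fat, was below 1 CPM in both stages in 4 lines and above 10 CPM in both stages in 12 lines. It stood at 0.0442 and 0.321 CPM in line C2 and at 55.8 and 66.2 CPM in line C6. Meg3, a maternally expressed noncoding RNA, was below 1 CPM in both stages in 10 lines and above 10 CPM in both in 7, with 157 and 42.0 CPM in line C4 and 0 and 0.0292 CPM in line A5, both values there below the limit of 3 counts. Rian, a noncoding RNA of the same imprinted cluster, ran from 0 and 0.0292 CPM in line A5 to 75.1 and 69.5 CPM in line D5, the highest line by mean log2 CPM over both stages, while its highest single library was that of undifferentiated C4 at 162 CPM. Thy1, a mesenchymal surface marker, ran from 0.0491 and 0.0585 CPM in A5 to 604 and 38.4 CPM in B3. Eng, the endothelial and stromal receptor endoglin, ran from 1.22 and 0.716 CPM in A2 to 300 and 258 CPM in D5. The collagen gene Col1a2 ran from 1.19 and 14.9 CPM in A2 to 2349 and 5450 CPM in C6, and the progenitor marker Cd34 from 1.21 and 0.469 CPM in B6 to 454 and 291 CPM in C3.

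In all, 4041 of 14081 genes (28.7%) differed between lines in edgeR's quasi-likelihood test of the 19 line coefficients next to the stage. A gene detected in 1 stage only can be called from that stage alone. The smallest adjusted p among the genes named was 9.40e-11 (Eng), and those of Zic1 and Meg3 were 5.62e-06 and 1.06e-08. The called genes had a median SD between lines of 0.342 on the log2 scale and a median SD within lines of 0.169. The other genes of largest spread were Rpl39l, Cthrc1, Efemp1, Nmral1, Plac8, Asb4, Irx1 and Arhgef5, with ranges of 7.67 to 10.52 on the log2 scale over the lines. Of the subtype genes, Eif5, Tcf25 and Bin1 all differed, with ranges of 0.87, 0.89 and 1.48 on the log2 scale and adjusted p of 0.000705, 0.000292 and 0.00490. Pparg was not called (adjusted p = 0.120 in edgeR), although DESeq2 and limma-voom called it with adjusted p of 0.00430 and 0.00297, and it was 0.00297 to 0.133 over the alternatives. Among sex-linked genes Ddx3y was listed at 0 in all libraries, which does not tell absent expression from a symbol that the counting did not cover, and Xist stayed below 1 CPM in all 20 lines in both stages, whereas Eif2s3y, Uty and Kdm5d differed between lines.

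Line differences were unevenly spread over gene groups. Of 29 Hox genes 23 differed between lines, more than in each of 10000 random lists matched on expression (median 27.6%). The 6 not called were Hoxa2, Hoxb2, Hoxb3, Hoxb4, Hoxb6 and Hoxb9, named after their values were seen. Hoxc8 and Hoxc6 had the widest spread, with SDs between lines of 2.37 and 2.34 on the log2 scale. Both 3-gene lists, sex-linked and subtype, had 3 of 3 called. The white and beige list (11 of 16 genes, percentile 99.8), the adipocyte list (12 of 24, percentile 98.2) and the thermogenic list (9 of 17, percentile 97.2) also had many calls, but those of Cfd and Lep, with 0 counts before differentiation, and of Slc36a2, Cd36, Plin1, Cidea and Adipoq, with 2, 4, 6, 6 and 8, rest on 1 differentiated library per line and show no difference beyond the stage. In contrast, none of 20 fatty acid oxidation genes, 22 tricarboxylic acid cycle genes and 43 respiratory chain genes was called, all 3 lists at or below percentile 0.1, and lipogenesis had 1 of 16 (percentile 3.03). At an SD between undifferentiated lines of 0.221, 0.187 and 0.187 and between differentiated lines of 0.651, 0.636 and 0.495 (medians, log2 scale), members of the first 3 lists varied more after differentiation. For genes detected in both stages, a spread that arises in 1 stage only adds to the error of the line test. The absence of calls in these lists therefore does not show that the lines were alike. The random lists were matched on expression and not on this error.

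**Figure D3:**
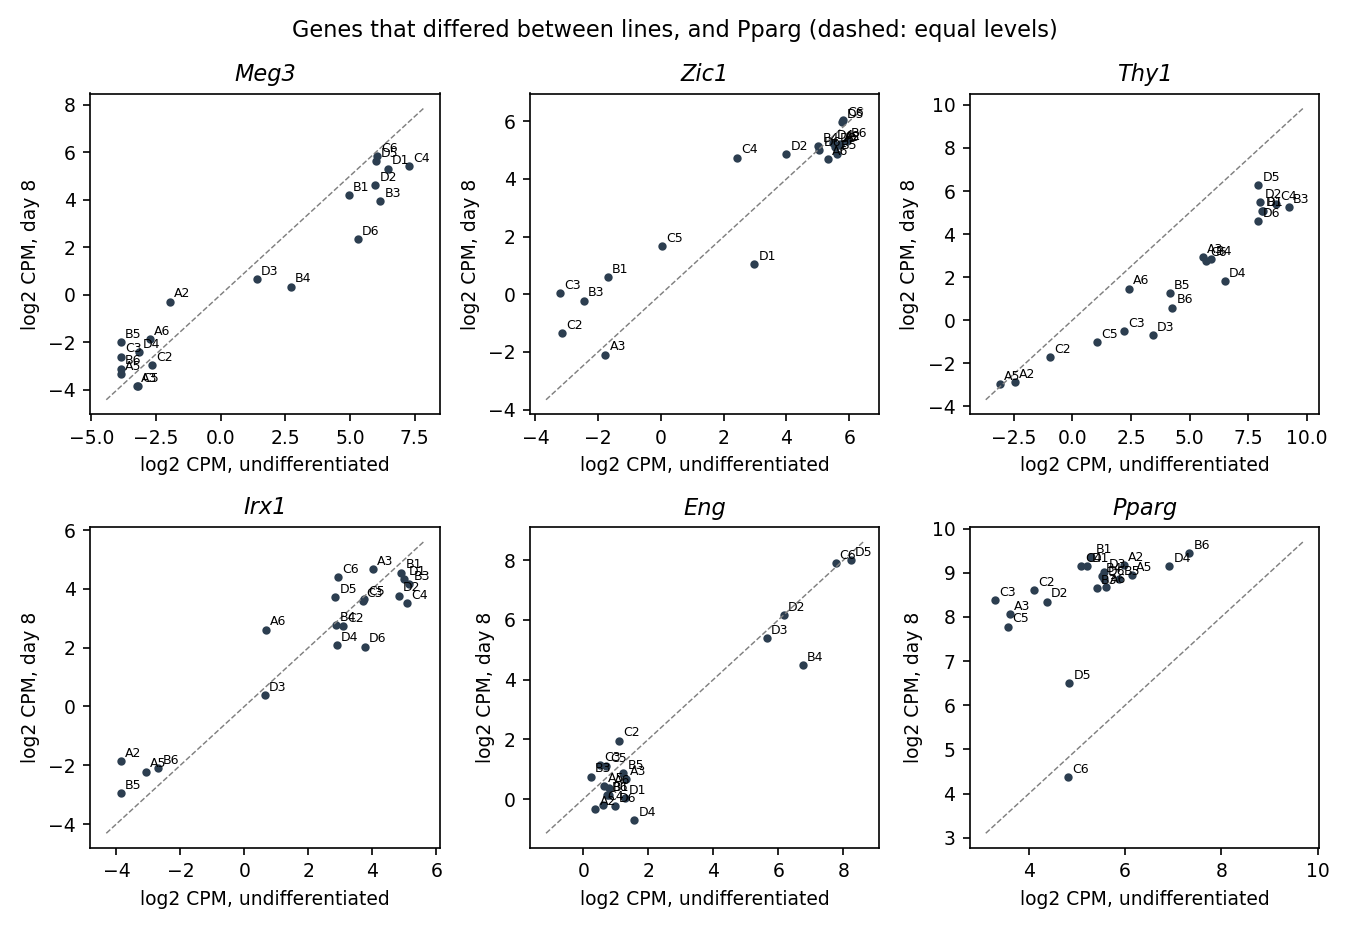
Log2 CPM in undifferentiated cells (horizontal axis) against log2 CPM at day 8 (vertical axis) for 6 genes, with 1 labelled point per cell line and a dashed line of equal levels. Meg3 and Zic1 separate the lines in both stages, with 10 and 4 lines below 1 CPM in both, whereas Pparg was not called between lines by edgeR (DESeq2 and limma-voom called it).

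Each line kept a recognisable profile through differentiation. After removal of the stage means, the undifferentiated and differentiated libraries of a line correlated across the 1000 most variable genes at a mean r of 0.524, from 0.336 in D6 to 0.645 in A2, against a mean of -0.0268 with other lines. The permutation of lines gave a one-sided p of 1e-05, the smallest that 100000 draws can give. Of the 20 differentiated libraries, 19 correlated best with the undifferentiated library of their own line, and that of D1 correlated at 0.477 with its own and 0.484 with C4. Genes are not independent replicates in these correlations.

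**Figure D4:**
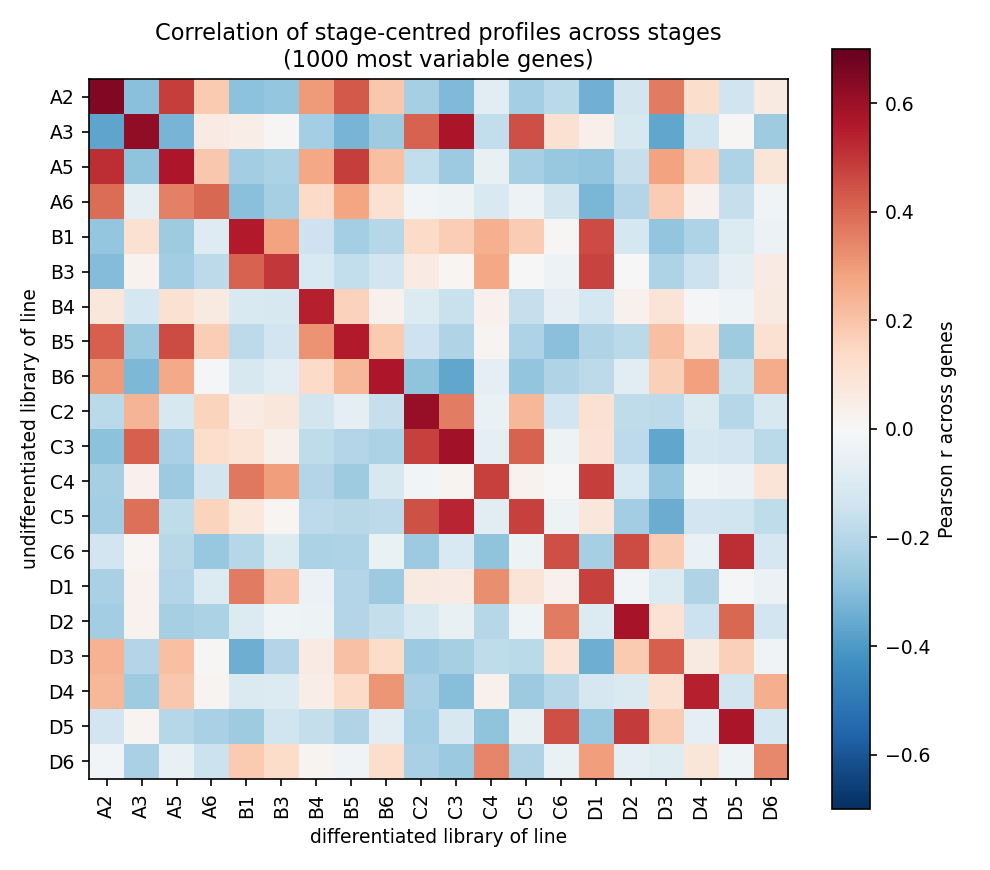
Pearson correlation across 1000 genes (colour) between the stage-centred profiles of each undifferentiated library (rows) and each differentiated library (columns). The diagonal holds the 2 libraries of the same line and runs from 0.336 to 0.645.

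Lines lay further apart after differentiation. The SD between lines was larger in the differentiated libraries for 68.1% of 9764 genes, with a median ratio of 1.22 and a permutation p of 0.00180 (two-sided, 10000 draws). The widening was largest in metabolic lists, at a median ratio of 3.30 for the tricarboxylic acid cycle, 2.68 for fatty acid oxidation and 2.60 for the respiratory chain. The median ratio was 0.938 for Hox genes, 1.06 for the white and beige list and 0.678 for 4 pericyte and smooth muscle genes. The difference between lists was not tested.

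The third set of comparisons asked whether undifferentiated cells carried expression related to how far their line later differentiated. Of 12409 genes in the 20 undifferentiated libraries, 520 had a positive and 433 a negative slope on the later adipocyte score of the line, the mean z-score of the adipocyte list at day 8. The basement membrane gene Nid1 (log2 slope 0.29, SE 0.04), the lysosomal oxidase gene Pcyox1 (0.22, SE 0.03) and the calcium channel gene Itpr2 (0.55, SE 0.09) were higher in lines with a higher later score. Cldn15 and Elf4 were also positive, at 0.88 (SE 0.14) and 0.23 (SE 0.04). Pcyt2, an enzyme of phosphatidylethanolamine synthesis, had a slope of -0.33 (SE 0.04), and Prpf40b, Tmeff1, Cpxm1 and AA408296 had slopes of -0.31, -0.65, -1.16 and -0.19. The adjusted p of these 10 genes ran from 0.000207 to 0.00238 in edgeR. Their Spearman correlations with the score had the sign of the slope, but were weak for Cpxm1 (-0.167) and Pcyt2 (-0.450). The count rested on the lines C6 and D5: it was 134 without C6, 272 without D5 and 10 without both.

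On later Ucp1, 298 genes of the undifferentiated libraries had a positive and 406 a negative slope per log2 unit. The low end of this covariate lay near the floor, with 0 Ucp1 counts in C6, 2 in D5 and 3 in A3. The fit held no adipocyte score, which was lowest in C6 and D5, so it cannot part Ucp1 from the degree of differentiation. Positive genes included the histone demethylase gene Kdm3a (log2 slope 0.07, SE 0.01), the matrix gene Fbln2 (0.12, SE 0.02), Irak2 (0.14, SE 0.02), Ttll3 (0.18, SE 0.03) and Kbtbd2 (0.08, SE 0.01). Negative genes included Tmem97, Ddx56 and Mrpl12, a mitochondrial ribosomal protein, each at -0.09, and Tbc1d10a and AK133228 at -0.08 and -0.09. The adjusted p of these 10 genes ran from 0.00589 to 0.00807 in edgeR. Leaving out 1 line moved the count of 704 by over 1.5 times for D5 (288), A3 (303), D6 (357) and B3 (410), and it was 326 without B3 and B6.

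In the differentiated libraries, 275 genes rose and 51 fell with Ucp1 at equal adipocyte score. Cidea had the steepest slope of those named (log2 slope 0.93 per log2 unit of Ucp1, SE 0.09, adjusted p = 5.44e-05), followed by Mb, myoglobin (0.71, SE 0.08), and Cpt1b, which imports fatty acids into mitochondria (0.43, SE 0.06). Dlst and Hadhb, of the tricarboxylic acid cycle and fatty acid oxidation, had slopes of 0.19 each (SE 0.03). Gpr64, Mc2r, BC034902, Itga6 and Dram1 were negative, at -0.41, -0.25, -0.18, -0.18 and -0.16. Without the adipocyte score beside it, the Spearman correlation with Ucp1 was negative for Gpr64 (-0.475) and Dram1 (-0.177). It was not negative for BC034902 (0.171), Itga6 (0.0511) and Mc2r (0.00902). This count rested on few lines. It was 14 without B6, 128 without B3, 160 without C2, 202 without D6, 205 without D3 and 208 without A3, and 0 without B3 and B6.

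Across the 20 lines, Ucp1 at day 8 was related to 9 other measures. It followed the score of the other thermogenic genes of the same libraries (Pearson r = 0.865, Spearman rho = 0.863). Each permutation p was 1e-05, the smallest that 100000 draws can give, with an adjusted p of 9e-05, and r was 0.762 without C6 and B6, the lines farthest from the median of that score. With the adipocyte score, r was 0.569 (permutation p = 0.0132, adjusted 0.0397) and rho 0.579 (p = 0.00898, adjusted 0.0335). With Pparg at day 8, r was 0.599 (permutation p = 0.00810, adjusted 0.0364) and rho 0.561 (p = 0.0112, adjusted 0.0335). Both relations rested on C6 and D5, without which r was 0.366 and 0.422 and neither passed. With the extracellular matrix score, r was -0.517 (permutation p = 0.0186, adjusted 0.0419) and rho -0.496 (p = 0.0273, adjusted 0.0615), and without C6 and D4 r was -0.485 and did not pass. The cell cycle score at day 8 and the 4 measures of the undifferentiated libraries did not pass the adjustment. They were Pparg (r = 0.468, adjusted permutation p = 0.0573), the adipocyte score (r = 0.437, 0.0711), the preadipocyte score (r = 0.214, 0.414) and Ucp1 itself (r = -0.156, 0.514). For Ucp1 itself rho was of the other sign, at 0.0885. Relations within the 4 to 6 lines of a letter were not computed.

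**Figure D5:**
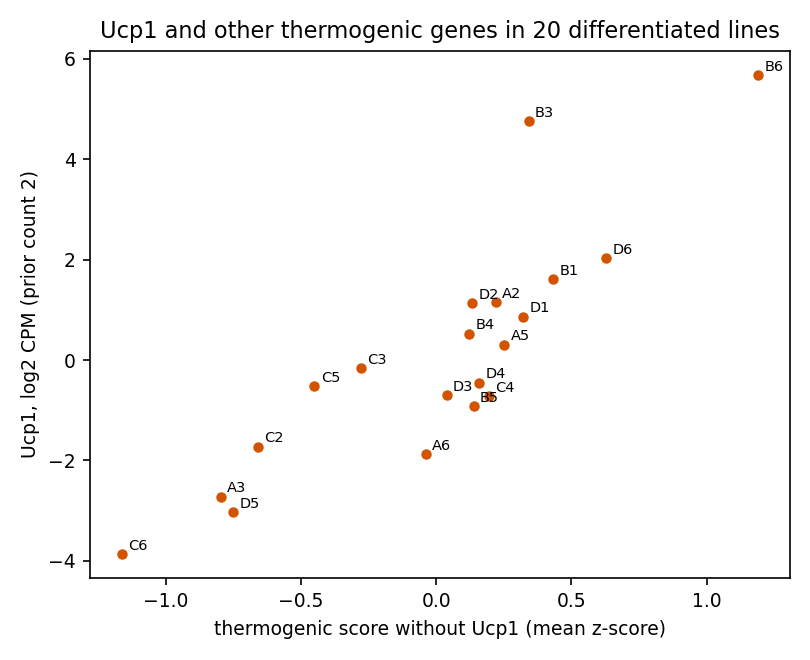
Ucp1 at day 8 (vertical axis, log2 CPM with a prior count of 2) against the mean z-score of the other thermogenic genes in the same library (horizontal axis), 1 labelled point per cell line. Ucp1 was highest in B6 and B3 and Pearson r over the 20 lines was 0.865.

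The letter of the line name was tested as a possible batch. No gene differed between the 4 letters in edgeR's quasi-likelihood test, in the undifferentiated libraries (0 of 12409) or in the differentiated ones (0 of 13248). At an unadjusted p under 0.05 there were 1232 genes (9.93%) and 1563 genes (11.8%), DESeq2 called 4 and 35 genes, and limma-voom called 0 and 0. Within the lines of 1 letter, the stage difference was called for 9118 genes in A, 9313 in B, 7960 in C and 8830 in D.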

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

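Among the tests below, that of the counting as the cause of the adipocyte rise and those on genes with pseudogene copies were chosen only after the results were seen.

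Some signal lay outside the gene counts used. Undifferentiated libraries held on average 735418 reads tallied as low quality and 243009 reads tallied as unaligned, and differentiated libraries 0 of either. Symbols listed in the files of only 1 stage held 768.45 reads per undifferentiated and 53.9 reads per differentiated library. Symbols left out because another differs from them only in letter case held 84802.9 reads per undifferentiated and 161178 reads per differentiated library.

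Genes with processed pseudogene copies rose as a set, with a median log2 change of 0.694 for the 694 genes with at least 10% of their 31-mers shared, against a highest median of 0.0832 in 10000 random lists. In single lines that median ran from 0.468 to 0.905. A rise of ribosomal protein genes in differentiation, as the whole account, was set against those genes themselves. The 67 that share at least 10% had a median log2 change of 2.95 and 7 that share less had 0.174. The difference was 2.78 (permutation p = 0.0119). This contrast cannot decide, since genes were picked by symbol, which can let in paralogues, and the permutation treats genes as independent. Reads shared with copies and assigned differently in the 2 stages may explain many steep rises, such as that of Gapdh. This account stays open, since the files hold no reads, and copies that the annotation does not list were not searched.

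The rise of the adipocyte list was weighed against the same difference in counting. Counting alone was predicted to give every line about the same rise, and the mean log2 rise of the list ranged over 5.56 between lines. It ran from 3.43 in C6 and 6.16 in D5 to 8.99 in B1, with the other lines at 7.44 or more. This range cannot decide on the counting: several members had next to no counts before induction. Their rise follows the day 8 level of a line under any counting. No member of the list shares 10% of its 31-mers with processed pseudogenes. A few abundant genes taking the counts are argued against, since the median log2 change was 8.19 with library sizes taken without the 50 most abundant genes and 8.20 with all. Differentiation, the difference that the design names, remains as a hypothesis for the rise, and the counting is not told apart from it.

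The lines kept their own profile across stages at a mean correlation of 0.524 (SD 0.0800 over 20 lines). It was 0.509 after thinning every library to 19461042 counts, which argues against depth. It was 0.0305 with other lines of the same letter, which argues against a batch shared within a letter. After removal of the median of each chromosome it was 0.511, against 0.515 on the same genes before, so these medians carried little of it. This could hardly come out otherwise. The largest shift, as the mean of both stages, was -0.578 (log2, chromosome 18 in D4), while 735 called genes had an SD between lines of at least 1. The removal cannot decide on copy number as a cause, since changes of parts of chromosomes were not removed. A lasting difference between lines, chromosome copy number included, is a hypothesis that remains. Next to it stands a culture history shared by the 2 libraries of a line, which the labels do not describe.

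Regroupings of the libraries were used to ask whether chance can be excluded. For the stage difference it can: 1 of 100 splits, the real one with 11562 genes, gave as many. The highest other split gave 8722 genes and had 16 of the 20 differentiated libraries on one side, so it largely followed the stage. Of 49 other splits that part every pair of libraries of a line, 47 gave 0 genes, and of 50 unrestricted splits 48 gave 0. For the line difference, 1 of 40 pairings of the libraries gave 4041 genes, the real one, and the highest other 132, so chance pairing can be excluded. For the later adipocyte score, 1 of 100 orders of the score gave 953 genes and the highest other 8. For later Ucp1, 2 of 100 orders gave 704 genes or more and the highest other 1454, so a chance order can give more genes than the real one. For Ucp1 at equal adipocyte score, 1 of 100 orders gave 326 genes and the highest other 282. These orders treat the 20 lines as independent. Under that assumption chance order is argued against for the later adipocyte score, where the highest other order gave 8 genes. For the 2 counts on Ucp1 it is not excluded, since other orders gave up to 1454 and 282 genes. At equal adipocyte score, Ucp1 was reordered with the score kept, so those orders lack the relation between the 2. Nor is chance excluded for lines that resemble each other: C6 and D5, the lowest adipocyte scores, correlated at 0.888 and 0.910 in the 2 stages. Without both, the count of 953 was 10. Apart from that, the count at equal adipocyte score rests on the 2 lines with the highest Ucp1: it was 0 without B3 and B6. The count for later Ucp1 was 326 without these 2 lines and lower, at 288, without D5 alone. For the letters the real count in edgeR was 0 in both stages (1232 and 1563 genes at an unadjusted p under 0.05, 4 and 35 by DESeq2, 0 by limma-voom), so 100 of 100 assignments gave as many. The highest others were 257 in undifferentiated and 120 in differentiated libraries. The cause of those counts was not tested, and they say nothing for or against the letters.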

How the results depend on the processing

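Leaving out C6 and D5, leaving out A5, C5 and D5, keeping the case variants and leaving out genes with pseudogene copies were alternatives chosen only after the data were seen. None of the 10 steepest rises, the 10 steepest falls and the fixed markers of the stage reversed direction in the alternatives run for them. Nor did any called list or relation. The line test has no direction, and genes named for the covariates or only as list members were not checked for direction here. Between Pearson r and Spearman rho, the relation with Ucp1 before differentiation, which did not pass, changed sign (-0.156 and 0.0885). The medians of 5 lists without a call changed sign with the lines of 1 letter alone: preadipocyte (-0.26 to 0.25 in C), Hox (-0.28 to 0.10 in C), skeletal muscle (-0.48 to 0.07 in A), endothelial (0.50 to -0.14 in B) and sex-linked (-0.07 to 0.04 in C and 0.21 in D). The share of positive slopes did shift, from 54.6% to 38.3% with ranks and 20% without C6 and D5 for the later adipocyte score, and for Ucp1 at equal score from 84.4% to 63.5% in DESeq2, 100% with ranks and 48.2% without the adipocyte score. Of 261 values of the main comparisons under alternatives, 210 kept their call or lay within 1.5 times, and 51 moved. The stage difference called 11623 genes without C6 and D5, 10912 without genes with copies and 12056 with the line as a replicate block. With a log2 change of at least 1 it called 5333 genes (3330 that rose, 2003 that fell). DESeq2 called more genes than edgeR for the line difference (7007), the later adipocyte score (870 positive slopes), later Ucp1 (1145, 564 positive) and Ucp1 at equal adipocyte score (814, 517 positive and 297 negative), and 4 and 35 genes for the letters in undifferentiated and differentiated libraries. Without a count filter, later Ucp1 gave 447 genes (188 positive, 259 negative) and Ucp1 at equal adipocyte score 210 (180 and 30). With the covariate as a rank, the later adipocyte score gave 141 genes (54 positive, 87 negative) and Ucp1 at equal score 7 (7 and 0). Without the 2 lines farthest from the median, the later adipocyte score gave 10 genes without C6 and D5 (2 and 8), and without B3 and B6 later Ucp1 gave 326 (143 and 183) and Ucp1 at equal score 0 (0 and 0). Ucp1 without the adipocyte score beside it gave 4323 genes (2085 and 2238). Without C6 and D5 the line difference was 3122 genes, and without A5, C5 and D5, 1 line of each of the 3 closest pairs, 3050. The log2 spread ratio was 0.231 without C6 and D5 (permutation p = 0.00590), against 0.286.

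Leaving out 1 line at a time gave 11303 to 11533 genes for the stage, 3446 to 4062 for the line difference, 134 to 1059 for the later adipocyte score, 288 to 822 for later Ucp1, 14 to 483 for Ucp1 at equal score, 0.513 to 0.537 for the own-line correlation and 0.249 to 0.322 for the log2 spread ratio. Counts moved by over 1.5 times for the later adipocyte score without C6 (134) and D5 (272), for later Ucp1 without D5 (288), A3 (303), D6 (357) and B3 (410), and for Ucp1 at equal score without B6 (14), B3 (128), C2 (160), D6 (202), D3 (205) and A3 (208). Of the gene lists, 12 were called by camera with the preset correlation and 0 with an estimated one, with or without the replicate block; without genes with copies 11 were called. Over the 5 alternatives the adjusted p of the adipocyte list ran from 4.03e-14 to 0.503 and that of the other 11 called lists reached 0.503 to 0.543. The adjusted p of fry was under 0.05 for every list but skeletal muscle (0.236), endothelial (0.176) and sex-linked (0.830). That includes lists that camera did not call, such as Hox (fry adjusted p = 0.000277). fry does not ask whether a list moved more than other genes. Of the relations of Ucp1, 4 passed and 1 without the 2 farthest lines. Among named genes, Dio2 was called by DESeq2 (log2 fold change 2.94) and with the replicate block (1.48), Dlk1 was lost in limma-voom (0.96), and Pparg was called between lines by DESeq2 and limma-voom. The cause of these changes was not tested. With the replicate block 8 Hox genes rose and 14 fell, against 3 and 11; the counts of other lists changed by at most 1 gene in either direction, and no call of a list changed. Depth limits what can be said of genes near 3 counts per library, Ucp1 in most lines among them.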

Other observations

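Of the tests in this part, the relation of distances between lines was chosen only after the data were seen, as were the genes named here; that of the chromosome shifts was chosen before.

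Some imprinted genes were on or off by line and others on in every line; no list of imprinted genes was tested. Besides Meg3 and Rian, the noncoding RNA Mirg of the same cluster was below 1 CPM in both stages in 12 of 20 lines, reached 11.1 CPM at most over all libraries, and stood highest in line C4 over both stages. Dlk1, a protein-coding gene of that cluster, was above 10 CPM in both stages in 15 lines and below 1 CPM in both in 0. Peg10 and Sgce, of another imprinted cluster, were above 10 CPM in both stages in all 20 lines, whereas Asb4 of that cluster was below 1 CPM in both in 11 lines and above 10 CPM in both in 4, highest in C2. H19 was below 1 CPM in both stages in 15 lines and above 10 CPM in both in 0. Peg3, Igf2 and Mest fitted neither kind, with 0, 1 and 0 lines below 1 CPM in both stages and 2, 0 and 1 lines above 10 CPM in both.

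Hox and Zic1 levels marked partly the same lines. Hoxc6 and Hoxc8 were lowest in C2 and A3, which were also lowest for Zic1, and both were highest in C6 and D5. Hoxc8 was below 1 CPM in both stages in 5 lines and above 10 CPM in both in 5. Hoxc6 was below 1 CPM in both in 2 lines and above 10 CPM in both in 12. Whether this overlap exceeds chance was not tested.

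Whole chromosomes were shifted in single lines. In D4, the 325 tested genes assigned to chromosome 18 had a median level of 0.663 times the mean of all lines before and 0.677 times after differentiation. Chromosome 12 was raised in B1 (1.34 and 1.31 times), B6 (1.32 and 1.28 times) and D2 (1.29 and 1.21 times) and lowered in A2 (0.786 and 0.826 times), A5 (0.786 and 0.820 times) and B5 (0.794 and 0.825 times). Lines C6 and D5 shared lower medians of chromosomes 6 (0.798 and 0.786 times in C6, 0.802 and 0.771 times in D5) and 8 and a higher median of chromosome 1. Not every shift was kept: chromosome 12 in C4 stood at 1.25 and then 0.953 times, and in B3 chromosome 11 at 0.799 and then 1.06 times and chromosome X at a median log2 deviation of 0.26 and then -0.09. Gained or lost chromosomes kept through differentiation are a candidate explanation. They predicted that the medians per line and chromosome correlate between the stages, and they did so over 400 values at r = 0.780, against a highest r of 0.179 in 1000 shuffles of genes over chromosomes. In all, 127 of the 400 values lay beyond every shuffle in both stages, 67 higher and 60 lower, and each of the 20 lines had some. The largest shuffled value was a median log2 deviation of 0.0834, so the count includes small shifts. Chromosome 5 in D3, at 1.07 and 1.08 times, is 1 of them. The count is therefore not a count of gained or lost chromosomes. DNA was not measured here, so the hypothesis stays open.

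Some lines lay close to each other in both stages. C6 and D5 correlated at 0.888 before and 0.910 after differentiation over the 1000 most variable genes, C3 and C5 at 0.850 and 0.839, A2 and A5 at 0.735 and 0.803, and A5 and B5 at a mean of 0.761 over the stages. These were the 4 closest of 190 pairs in both stages. Distances between lines in the 2 stages correlated at 0.668, with a permutation p of 1e-04, the smallest that 10000 draws can give. C6 and D5 were also the lines with the smallest adipocyte rise.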
